A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

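Messenger RNA levels were measured in the budding yeast Saccharomyces cerevisiae, in the haploid laboratory strain BY4742, on 3 NimbleGen oligonucleotide arrays of 1 colour. The control array carried RNA from cells growing at 0.1 MPa, which is atmospheric pressure, and 24 °C. The high-pressure array carried RNA from cells held for 5 h at 25 MPa and 24 °C, and the low-temperature array RNA from cells held for 5 h at 0.1 MPa and 15 °C. Per the labels, the control culture was harvested at its growth density, and no 5 h incubation is stated for it. RNA of 3 cultures was pooled in equal parts for each condition before labelling, so each condition has 1 array and no replicate. The number of arrays limits the precision of every value, and no difference between conditions could be tested. The free-text sample descriptions name another strain and a growth temperature that conflict with the sample titles and the design text, so the strain was checked from the levels of marker genes.

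The main values are log2 expression levels, which per the labels were made by the authors with robust multiarray average (RMA) and quantile normalization. RMA is named in the submitters' processing notes as well, and its version is not given in the sources used here. Each gene is represented by 15 pairs of perfect-match and mismatch probes. The deposited per-array tables hold, for each gene, the mean perfect-match and mean mismatch intensity on a linear scale and the mean of their difference. Those deposited tables also give a coefficient of variation, the ratio of the standard deviation to the mean over the probes of a gene. The analysis plan took the per-array tables to hold the RMA values, but they hold these intensities, and the log2 table of the series holds the RMA values. The RMA values were therefore kept as the main values, and the planned exchange of the 2 sources was run with the perfect-match intensities as the alternative. Across genes, each RMA column correlated most closely with the log2 perfect-match intensity of its own array, with Pearson r of 0.932, 0.931 and 0.924 for the control, high-pressure and low-temperature arrays. How background was corrected and whether all 3 arrays were normalized together is not given in the sources used here. RMA pulls the distributions of the arrays towards each other at the level of probes, so a shift shared by most genes can be hidden or created by it.

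The arrays hold 6337 rows. Levels of 65 genes with more than 1 row, 132 rows in all, were averaged on the log2 scale, which left 6270 genes. Row names come from an older annotation and were matched to the RefSeq gene table of assembly R64, used for names and gene lengths alone. Of the rows, 1723 matched by locus tag, 3953 by symbol and 156 by synonym, and the other 505 kept the name in the files. No coordinates are given, since the genome build behind the probes is not given in the sources used here. Gene length was known for 92.0% of the genes.

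A gene was taken as above mismatch on an array when the mean difference of its 15 probe pairs exceeded 0 at a one-sided level of 5%, a t value above 1.76 with 14 degrees of freedom computed from the deposited mean and coefficient of variation. A few bright mismatch probes can keep a gene under this limit even where RMA gives it a high level. For a gene not above mismatch on the dimmer of the 2 arrays compared, the RMA ratio is given with "at least". These words mark that the dimmer level was not above mismatch. The value is the ratio of the deposited RMA values and no guaranteed minimum. Other scalings or the perfect-match intensities can give a smaller one. For a gene above mismatch on neither array, levels are given without a fold.

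For each comparison the log2 ratio was the difference of the levels of the 2 arrays. Genes were counted as higher or lower past 1.5-fold, the size named in the design text of the series, if the higher of their 2 levels was at or above the 25th percentile of that array. Such a count describes the arrays compared and is no test of the conditions. The median log2 ratio of 23 gene lists was placed among 10000 random lists of the same size matched on mean level in 20 bins, and lists beyond the 2.5 or 97.5 percentile are said to stand apart. By chance 1.15 of 23 lists would do so in each comparison if the members of a list varied independently. Members that vary together, such as near-identical genes, can make more lists stand apart without an effect of the condition. The lists were DAN/TIR mannoproteins, PAU seripauperins, hypoxic genes, ergosterol biosynthesis, other cell wall genes, heat shock proteins and chaperones, general stress and reserve carbohydrates, ribosome biogenesis, ribosomal proteins, amino acid permeases, amino acid biosynthesis, methionine and sulfur assimilation, phosphate response, iron uptake, glucose-repressed genes, hexose transport and glycolysis, respiration, fatty acid and phospholipid synthesis, histones, a-specific and alpha-specific mating genes, meiosis and sporulation, and markers deleted in BY4742. The chaperone gene SSA1 was not analysed here, as no row carried its name.

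The genes named are all DAN/TIR members and all markers deleted in BY4742; the 10 highest and 10 lowest log2 ratios of each comparison with the control; the 5 highest and 5 lowest of high pressure against low temperature; and the 2 members of every other list with the largest absolute log2 ratio in each comparison with the control. The highest and lowest genes were taken among genes whose higher level reached the median of its array. They were ordered by RMA log2 ratio, whether or not it is given with "at least", so their order is not exact. Design, lists, naming rule and a first set of alternative settings were fixed before the data were examined. Genes named outside this rule are said to have been chosen after their values were seen.

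Both responses use the same control array. Their overlap and correlation were therefore set beside 100 simulations of unchanged arrays against a shared control, with noise drawn from the differences between the 2 treated arrays. Those differences hold real effects too, and the noise of the control array itself was not measured. The 1.5-fold threshold, without the filter on dim genes, was tested on simulated data of 6270 genes with 200 changed genes. For high pressure against the control, 85.5% of the genes changed 2-fold and 99.5% of those changed 4-fold were recovered, and for low temperature 89.5% and 99%. Both simulated treated arrays carried the same changes, so the difference between these figures comes from random draws and not from the conditions. Between 10.9% and 12.2% of unchanged genes passed 1.5-fold in these simulations.

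Alternatives fixed in advance were a 2-fold and a 3-fold threshold, no filter on dim genes, a filter at the array median, arrays centred on their medians, quantile normalization of the gene values, 100 added to the linear values before log2, the first row of each gene and the other source of values. The perfect-match intensities as that source, a restriction to genes above mismatch, and the removal of a lowess trend (fraction 0.3) on mean level or on log2 gene length were settled after seeing the data. Centring shifts every ratio of a comparison by the same amount, so counts and signs can change but the percentile of a list does not. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.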

Results

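The series asked how yeast genes for cell wall mannoproteins of the DAN/TIR family respond to high hydrostatic pressure and to low temperature. It holds 3 arrays, 1 for each of control, high pressure (25 MPa) and low temperature (15 °C), each with RNA pooled from 3 cultures. There are no replicates, so the values below describe these arrays. The median log2 level over 6337 rows was 6.43 on the control array, 6.77 on the high-pressure array and 6.98 on the low-temperature array. The median perfect-match intensity was 278, 327 and 400, against a median mismatch intensity of 172, 165 and 178. Perfect-match probes exceeded their mismatch probes for 54.2% of rows on the control array, 62.4% on the high-pressure array and 60.5% on the low-temperature array.

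The markers deleted in BY4742 and the mating-type genes were read first, as a check of the strain. LYS2, a lysine synthesis gene, had log2 levels of 4.14, 4.08 and 3.75 on the control, high-pressure and low-temperature arrays, at the 5.15, 3.62 and 1.08 percentiles of each array. URA3, of uracil synthesis, lay at 5.17, 3.96 and 4.00. LEU2, of leucine synthesis, lay at 6.01, 6.92 and 7.58, up to the 62.2 percentile. None of these 3 genes was above mismatch on any array, so no fold is given for them. HIS3, of histidine synthesis, was above mismatch on all 3 arrays at 7.12, 8.34 and 7.75. Whether its probes lie in the deleted part of the gene was not tested, so this signal cannot speak for or against the label. Alpha-specific mating genes were bright: MF(ALPHA)1, an alpha-factor gene, lay at 13.43, 13.21 and 12.89. Of the a-specific genes of the other mating type, STE2, the alpha-factor receptor, lay at 5.38, 5.83 and 5.70 but above mismatch on all 3 arrays, and AGA2, a subunit of the a-agglutinin, was above mismatch on the control and high-pressure arrays at 6.23 and 5.90. MFA2, an a-factor gene, lay at 9.06, 9.05 and 9.06, at the 83.2, 81.6 and 81.8 percentiles, and ASG7 at 5.05, 5.56 and 5.72, with neither above mismatch on any array.

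High pressure was first set against the control. DAN1, a mannoprotein of the wall of anaerobic cells, was named for its high ratio, with a log2 level of 13.42 under pressure and 7.02 in the control, a log2 ratio of 6.40 and at least 84.4-fold higher on the RMA scale, but 4.94 on the log2 scale with perfect-match intensities. TIR1, a cold-shock and anaerobic mannoprotein, was at 4.94 (at least 30.6-fold higher by RMA), but 3.17 with perfect-match intensities. Of 33 ratios given here with "at least", 30 were smaller with those intensities. The words mark a dimmer level that was not above mismatch, not a guaranteed minimum. TIR4 was higher by 2.95 on the log2 scale (7.74-fold), TIR3 by 2.71 (at least 6.56-fold) and TIP1, the brightest of the family at a level of 14.48 under pressure, by 2.33 (5.03-fold). TIR2 had a level of 10.42 under pressure and 8.01 in the control, but was above mismatch on neither array. DAN4 and DAN3 had log2 ratios of 0.32 and 0.09, inside 1.5-fold, and DAN2 lay at 6.99 and 6.78, above mismatch on neither array. In all 6 of the 9 DAN/TIR genes were higher and 0 lower, with a median log2 ratio of 2.41 against 0.08 for matched random lists (percentile 100). That median is the ratio of TIR2, which was above mismatch on neither array. It was 2.03 with perfect-match intensities and 2.71 among the 7 members above mismatch. Among the 7 members above mismatch on either array, 5 were higher. The count over all 9 members was also 6 with the arrays centred on their medians and with quantile normalization of the gene values. The title of the study names this family, so its count is not independent evidence.

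**Figure D1:**
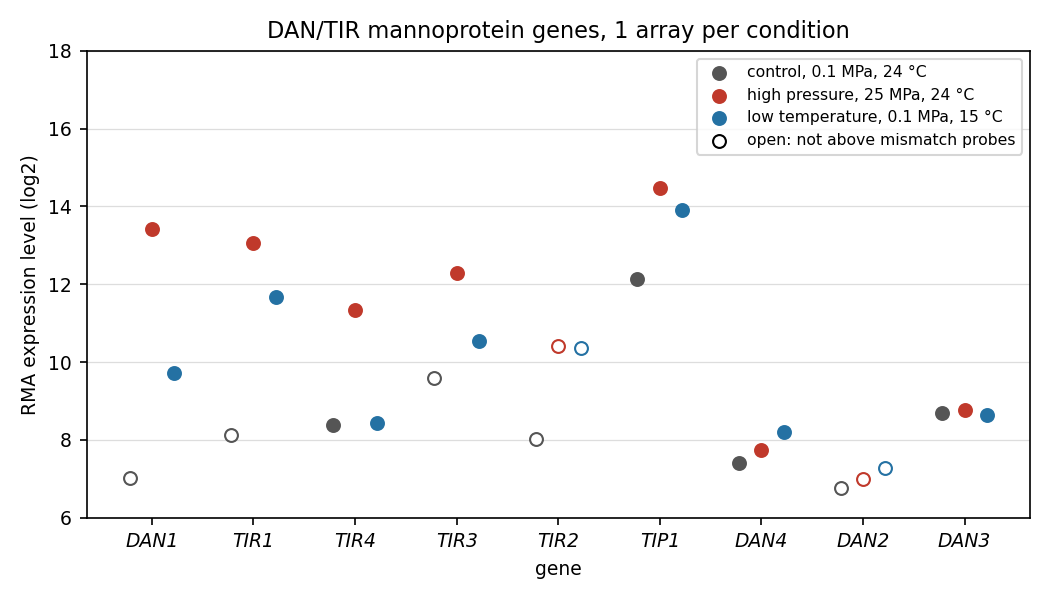
Log2 RMA level (y axis) of the 9 DAN/TIR genes (x axis) on the control, high-pressure and low-temperature arrays, 1 point per array, with open points for genes not above their mismatch probes. DAN1 lies at 7.02, 13.42 and 9.73 on these arrays and TIR4 at 8.40, 11.35 and 8.44, while DAN3 lies at 8.68, 8.78 and 8.64.

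STF2, a small protein that binds the ATP synthase inhibitor, was higher under pressure by 4.09 on the log2 scale (17.0-fold). COX5B, the hypoxic form of a cytochrome c oxidase subunit, was higher by 3.79 (at least 13.8-fold), and COX17, a copper chaperone for the same enzyme, by 3.24 (at least 9.47-fold). RGI1, named for its induction in respiratory growth, was higher by 3.23 (9.37-fold), EGO4 by 3.69 (at least 12.9-fold) and IMD2, an enzyme of guanine nucleotide synthesis, by 3.20 (9.17-fold). HMRA2, at a silent mating cassette and identical in sequence to part of the alpha2 gene that this mating type expresses, was higher by 3.20 (9.18-fold). GPG1 had levels of 10.24 and 6.39 and was above mismatch on neither array. Among the 13 hypoxic genes 8 were higher and 0 lower, with a median of 0.74 against 0.13 for random lists (percentile 99.3) and of 0.40 with the arrays centred, and FET4, a low-affinity iron transporter, was higher by 2.51 (5.69-fold).

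At the low end under pressure, DBP2, an RNA helicase of ribosome biogenesis, had a log2 ratio of -4.44 (at least 21.6-fold lower by RMA, but -1.69 on the log2 scale with perfect-match intensities), FET3, the oxidase of high-affinity iron uptake, -3.83 (14.3-fold lower) and HXT2, a hexose transporter, -3.55 (11.7-fold lower). AAH1, an adenine deaminase, had -3.29 (at least 9.77-fold lower) and NDE1, a mitochondrial NADH dehydrogenase, -3.27 (at least 9.64-fold lower by RMA, but -0.90 with perfect-match intensities). The amino acid permease genes TAT1 and BAP2, which lie on chromosome II, had -2.90 (7.46-fold lower) and -2.77 (6.83-fold lower). PRM7 and BSC1, both on chromosome IV, had -3.05 (8.27-fold lower) and -2.76 (at least 6.75-fold lower), and DDR2, a stress-response gene, -2.80 (at least 6.97-fold lower). Of 16 amino acid permease genes, 12 were lower and 0 higher, with a median of -1.40 against 0.10 for random lists (percentile 0) and of -0.81 with perfect-match intensities. Ribosome biogenesis genes were lower for 14 of 21 and higher for 2, with a median of -0.67 against 0.12 (percentile 0), but for 17 with the arrays centred and for 7 with a median of -0.26 with perfect-match intensities. NSR1, a nucleolar protein, had -2.38 (5.20-fold lower). Iron uptake genes were lower for 6 of 11 and higher for 0, with a median of -0.78 (percentile 0.01) that was -0.19 with perfect-match intensities, FTR1, the iron permease, at -2.16 (at least 4.47-fold lower) among them.

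Of 21 heat shock and chaperone genes, 13 were higher and 1 lower under pressure, with a median of 1.09 against 0.13 (percentile 99.99). With the arrays centred 11 were higher and 2 lower with a median of 0.75, and the lowest median of any alternative was 0.65. HSP104, a protein disaggregase, was higher by 1.98 (3.94-fold) and HSP10, a mitochondrial chaperonin, by 1.85 (3.61-fold). General stress and reserve carbohydrate genes were higher for 13 of 24 and lower for 3, with a median of 0.68 (percentile 99.7), but for 9 and 4 with a median of 0.34 with the arrays centred. GSY1, a glycogen synthase, was higher by 2.03 (at least 4.08-fold), whereas DDR2 of the same list was among the lowest genes. Fatty acid and phospholipid genes were higher for 6 of 12 and lower for 2, with a median of 0.70 (percentile 99.2) that was 0.36 with the arrays centred. Of these OPI3, a methyltransferase of phosphatidylcholine synthesis, was higher by 3.12 (8.71-fold) and ELO2, a fatty acid elongase, had -1.54 (2.90-fold lower). Histone genes were higher for 4 of 10 and lower for 1, with a median of 0.52 (percentile 98.0), but higher for 1 and lower for 3 both with the arrays centred (median 0.18) and without the trend on gene length (median 0.12, percentile 93.8). HHF1 and HHF2, both of histone H4, had 1.04 (2.06-fold) and 0.91 (1.88-fold). Ribosomal protein genes had a median of 0.09 (percentile 99.0), with 21 of 137 higher and 5 lower, but 12 higher and 32 lower with a median of -0.25 with the arrays centred and of -0.22 (percentile 87.9) without the length trend. RPS30A and RPL35B had the largest ratios there, 1.91 (3.76-fold) and 1.49 (2.80-fold).

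The remaining lists did not stand apart from random lists under pressure, except where said. Ergosterol genes were higher for 7 of 22 and lower for 1 (percentile 57.6), but for 3 and 5 with the arrays centred, ERG28 at 2.83 (7.13-fold) and ERG20, the farnesyl diphosphate synthase, at 1.42 (2.67-fold). Other cell wall genes were higher for 1 of 23 and lower for 8 (percentile 5.19), but without the length trend the list stood apart with a median of -0.59 (percentile 0.48), with CWP1, a wall mannoprotein, at -1.65 (3.14-fold lower) and GSC2, a glucan synthase subunit, at -1.60 (3.02-fold lower). PAU seripauperins, near-identical genes related to the DAN/TIR family for which probes can read transcripts of related copies, were higher for 1 of 21 (percentile 77.9), and PAU1 and PAU14 lay at 8.77 and 8.79 under pressure against 8.16 and 8.23, above mismatch on neither array. Methionine and sulfur genes were higher for 6 of 15 and lower for 1 (percentile 75.5), with MET16 at 2.01 (4.04-fold) and MET14 at 1.68 (3.22-fold), both of sulfate assimilation. Phosphate-response genes were higher for 4 of 12 and lower for 2 (percentile 88.3), with 3 and 3 when the arrays were centred, the acid phosphatases PHO5 at 1.69 (3.23-fold) and PHO12 at 1.56 (2.95-fold). Amino acid biosynthesis genes were higher for 5 of 20 and lower for 4 (percentile 52.8), but for 2 and 5 with the arrays centred, ARG4 at 1.73 (at least 3.32-fold) and LYS4 at -1.41 (2.66-fold lower). Respiration genes were higher for 5 of 21 and lower for 8 (percentile 11.4), COX7 at 1.65 (3.13-fold) and ATP2 at -1.34 (2.53-fold lower). Hexose transport and glycolysis genes were lower for 3 of 20 and higher for 0 (percentile 27.1), HXT1, a low-affinity glucose transporter, at -1.72 (3.29-fold lower). Glucose-repressed genes were lower for 3 of 14 (percentile 9.28), including HXT6 and HXT7 at -0.71 and -0.80, which were -0.074 and -0.37 with perfect-match intensities. Alpha-specific genes were higher for 1 of 4 (percentile 64.2; STE3, the a-factor receptor, at 0.92), a-specific genes for 0 of 7 (percentile 19.98), meiosis genes were lower for 1 of 11 (percentile 29.2), and SPS4 there had -0.73 (at least 1.66-fold lower by RMA, but -0.17 with perfect-match intensities) while DIT1 lay at 4.18 and 4.50, above mismatch on neither array. The markers deleted in BY4742 had a percentile of 86.7. Over the alternatives, the median ranged from -0.69 to 0.017 for glucose-repressed genes and from -0.48 to 0.11 for respiration genes. It ranged from -0.41 to 0.24 for hexose transport and glycolysis genes and from -0.10 to 0.59 for methionine and sulfur genes.

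In all, 1376 genes were higher and 599 lower under pressure past 1.5-fold among 4902 counted, and 10 of 23 lists stood apart. Simulated unchanged arrays, whose noise holds real effects too, gave means of 339 higher and 335 lower (at most 383 and 381). The median gene had a log2 ratio of 0.13 (SD over genes 0.75), and each log2 ratio above is 0.13 smaller relative to that gene. Centring the arrays on their medians moved the median ratio to -0.21 and the split to 840 higher and 1231 lower, quantile normalization of the gene values gave 1003 higher and 917 lower, and perfect-match intensities 1191 and 257. The split between higher and lower genes therefore rests on the scaling.

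Low temperature was then set against the same control. EGO4 had a ratio of 5.54 on the log2 scale (at least 46.6-fold), RGI1 of 5.15 (35.5-fold) and STF2 of 4.93 (30.5-fold). COX5B was higher by 4.04 (at least 16.5-fold), CYC7, the hypoxic form of cytochrome c, by 3.50 (at least 11.3-fold) and COX17 by 3.34 (at least 10.2-fold). PBI2, an inhibitor of a vacuolar proteinase, was higher by 3.66 (12.6-fold), YEL073C by 3.51 (at least 11.4-fold) and GSY1 by 3.28 (at least 9.74-fold). Of the DAN/TIR family, TIR1 was higher by 3.54 (at least 11.6-fold), DAN1 by 2.70 (at least 6.51-fold), TIP1 by 1.75 (3.37-fold), TIR3 by 0.94 (at least 1.92-fold) and DAN4 by 0.80 (1.74-fold), the last 2 inside 1.5-fold at 0.39 and 0.25 with the arrays centred. TIR2 had a level of 10.36 against 8.01, above mismatch on neither array. TIR4 and DAN3 had log2 ratios of 0.04 and -0.05, and DAN2 lay at 7.27 against 6.78. The family had 6 of 9 members higher and 0 lower, with a median of 0.94 against 0.11 for random lists (percentile 99.4). With the arrays centred this became 4 higher and 1 lower with a median of 0.39. The caution on a family named in the study's title holds here too.

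At the low end in the cold were DBP2 at -3.02 (at least 8.10-fold lower by RMA, but -0.85 with perfect-match intensities), PRM7 at -2.95 (7.75-fold lower) and BSC1 at -2.66 (at least 6.30-fold lower). The hexose transporter genes HXT1 and HXT2 had -2.58 and -2.34 (5.07-fold lower for HXT2), AAH1 had -2.56 (at least 5.92-fold lower) and TAT1 -2.22 (4.65-fold lower). RPA135, a large subunit of RNA polymerase I, had -2.33 (5.03-fold lower), MIS1, a mitochondrial enzyme of folate metabolism, -2.22 (4.64-fold lower) and URA7, a CTP synthase, -2.16 (4.48-fold lower). Of the amino acid permease genes, 10 of 16 were lower and 0 higher, with a median of -0.84 against 0.03 (percentile 0.02), but 4 were lower with a median of -0.12 with perfect-match intensities and all 16 with -1.38 with the arrays centred, BAP2 at -1.90 (3.72-fold lower) among them. Ribosome biogenesis genes were lower for 10 of 21 and higher for 1, with a median of -0.56 against 0.18 (percentile 0), but the median was 0.070 with perfect-match intensities and -1.10 with the arrays centred. NOG1, a GTPase of ribosome assembly, had -1.70 (at least 3.25-fold lower). Amino acid biosynthesis genes were lower for 6 of 20 and higher for 0, with a median of -0.29 (percentile 1.31), but the median was 0.20 with perfect-match intensities, 14 were lower with the arrays centred, and without the length trend the list did not stand apart (percentile 3.47). ILV2 and LEU1, of branched-chain amino acid synthesis, had -1.84 (3.58-fold lower) and -1.74 (3.34-fold lower).

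Stress and reserve carbohydrate genes were higher for 18 of 24 and lower for 0 in the cold, with a median of 1.17 against 0.06 (percentile 100) that was 0.62 with the arrays centred. HXK1, a hexokinase of this list, was higher by 3.06 (8.37-fold). Heat shock and chaperone genes were higher for 13 of 21 and lower for 1, with a median of 0.98 (percentile 99.97), but for 8 and 4 with a median of 0.43 with the arrays centred. HSP12, a membrane-associated stress protein, was at 2.13 (4.37-fold) and HSP104 at 1.91 (3.76-fold). Hypoxic genes were higher for 8 of 13 and lower for 0, with a median of 0.69 (percentile 97.7), but higher for 4 and lower for 4 with the arrays centred (median 0.14), and for 5 and 3 with quantile normalization of the gene values. Fatty acid and phospholipid genes were higher for 6 of 12 and lower for 2, with a median of 0.58 (percentile 98.1), but for 2 and 2 with a median of 0.033 with the arrays centred. OPI3 was at 3.16 (8.95-fold) and INO1, the inositol phosphate synthase, at 2.63 (at least 6.19-fold). Histone genes were higher for 7 of 10 and lower for 0, with a median of 0.80 (percentile 99.8), but for 1 and 1 both with the arrays centred (median 0.26) and without the length trend (0.22). HHF1 was at 1.41 (2.66-fold) and HHF2 at 1.10 (2.15-fold). The alpha-specific genes SAG1, the alpha-agglutinin, and MF(ALPHA)2 had -1.71 (3.27-fold lower) and -1.41 (2.66-fold lower), and their list of 4 had 2 lower, 0 higher and a median of -0.98 (percentile 0.23) that was -0.21 with perfect-match intensities. Ribosomal protein genes had a median of 0.32 (percentile 100), with 40 of 137 higher and 1 lower, but 15 higher and 35 lower with a median of -0.23 with the arrays centred and -0.20 without the length trend. RPL22B and RPL41B were higher by 2.26 (4.78-fold) and 1.83 (3.57-fold).

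Lists that did not stand apart in the cold included PAU seripauperins, with 8 of 21 higher (percentile 96.2) but 1 with the arrays centred, PAU22 at 1.18 (at least 2.26-fold by RMA, but 0.19 with perfect-match intensities) and PAU7 at 1.00 (2.00-fold). Glucose-repressed genes were higher for 5 of 14 and lower for 1 (percentile 89.9), HXT6 at 1.73 (3.32-fold) and HXT7 at 1.57 (2.96-fold). Ergosterol genes were higher for 4 of 22 and lower for 6 (percentile 14.2), but for 2 and 12 with the arrays centred and 10 and 0 with perfect-match intensities, ERG28 at 2.20 (4.59-fold) and ERG20 at 1.29 (2.44-fold). Other cell wall genes were higher for 5 of 23 and lower for 6 (percentile 6.55), but for 1 and 14 centred and 9 and 0 with perfect-match intensities, PIR3, a wall protein, at 1.83 (3.55-fold) and FKS1, a glucan synthase subunit, at -1.17 (2.25-fold lower), which was -0.23 with perfect-match intensities. Iron uptake genes were lower for 4 of 11 and higher for 0 (percentile 8.95), but for 1 and 2 with perfect-match intensities, FRE1, a ferric reductase, at -1.86 (at least 3.62-fold lower by RMA, but -0.85 with those intensities) and FET3 at -1.21 (2.32-fold lower), which was -0.23 with those intensities. Methionine and sulfur genes were higher for 5 of 15 and lower for 2 (percentile 45.5), but for 3 and 6 centred, MET16 at 1.83 (3.54-fold) and MET14 at 1.48 (2.78-fold). Phosphate-response genes were higher for 6 of 12 and lower for 2 (percentile 87.2), but for 3 and 3 centred, PHO12 at 1.24 (2.37-fold) and SPL2 at 1.17 (at least 2.25-fold). Respiration genes were higher for 6 of 21 and lower for 2 (percentile 32.0), but for 3 and 9 centred, COX7 at 1.78 (3.44-fold) and QCR8 at 1.43 (2.69-fold). Hexose transport and glycolysis genes were higher for 1 of 20 and lower for 2 (percentile 6.65), but for 1 and 14 centred and 8 and 2 with perfect-match intensities. Of the a-specific genes 1 of 7 and of the meiosis genes 1 of 11 were higher (percentiles 4.12 and 46.9), ASG7 and SPO13 respectively, which were above mismatch on neither array. The markers deleted in BY4742 had a percentile of 32.5.

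Among 4877 genes counted, 1695 were higher and 468 lower in the cold past 1.5-fold, and 11 of 23 lists stood apart. The median gene had a log2 ratio of 0.26 (SD over genes 0.73), to be subtracted for ratios relative to that gene. Centring moved the median ratio to -0.29 and the split to 721 higher and 1497 lower, quantile normalization gave 991 and 969, and perfect-match intensities gave 2259 and 113.

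**Figure D2:**
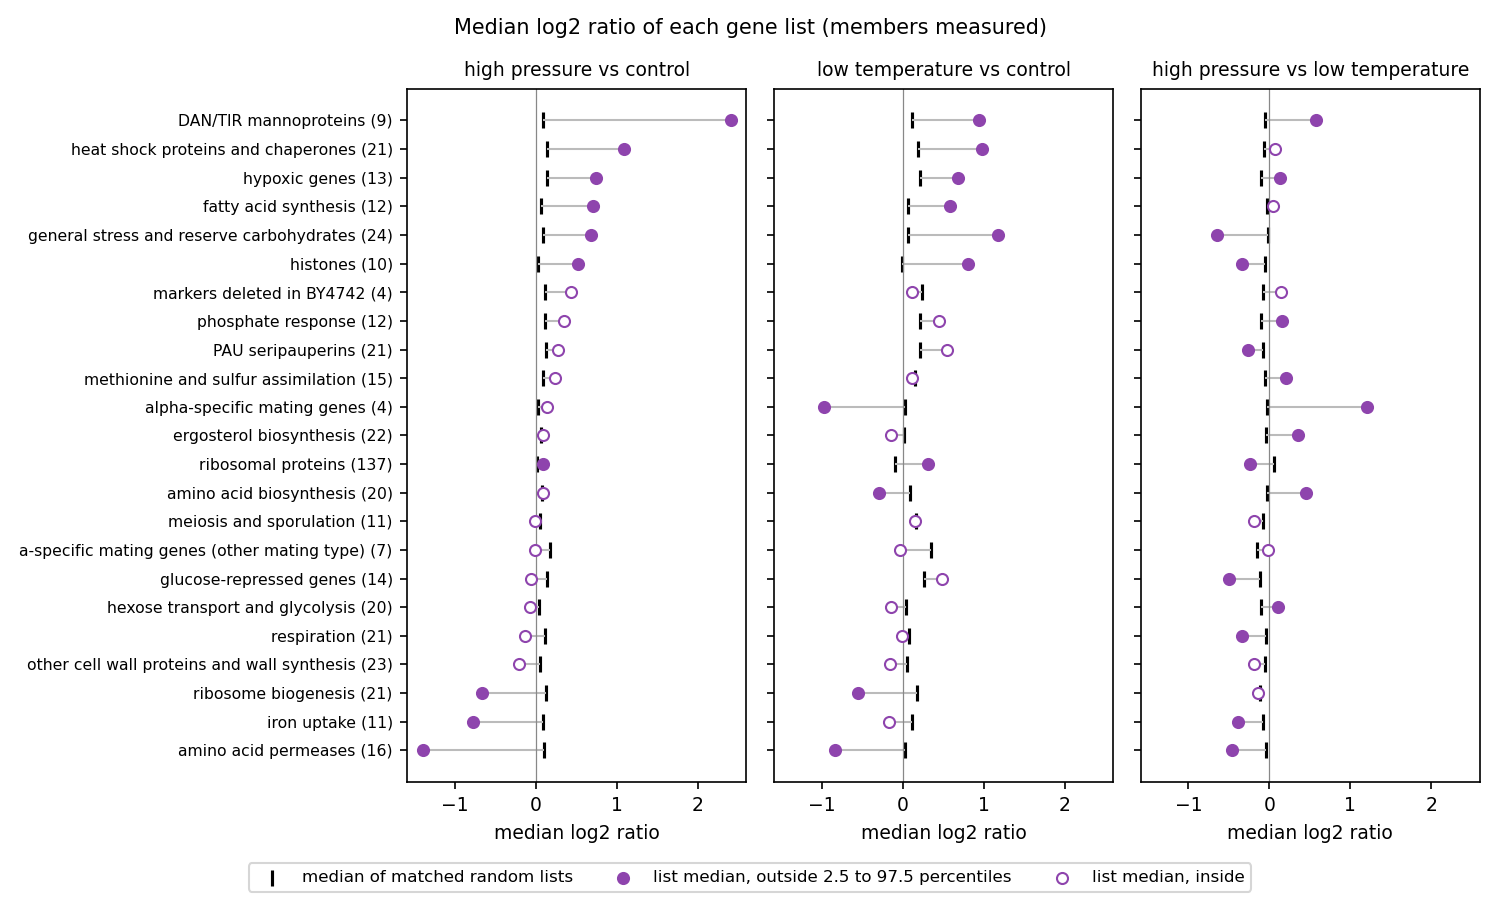
Median log2 ratio (x axis) of the 23 gene lists (y axis, members measured in parentheses) in the 3 comparisons, with filled points for lists that stood apart from matched random lists and black ticks for the median of those lists. DAN/TIR genes have the highest median under pressure (2.41) and amino acid permeases the lowest (-1.40). The ribosomal protein medians of 0.09 and 0.32 against the control turn to -0.25 and -0.23 with the arrays centred, where the median gene lies at -0.21 and -0.29.

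High pressure was set directly against low temperature, a comparison of arrays whose cultures were both held for 5 h. DAN1 was higher under pressure by 3.70 on the log2 scale (13.0-fold), TIR4 by 2.91 (7.52-fold), IMD2 by 1.87 (3.64-fold), TIR3 by 1.77 (3.41-fold) and SAG1 by 1.76 (3.39-fold). At the low end were DDR2 at -2.78 (at least 6.89-fold lower under pressure), RTN2, a membrane-shaping reticulon, at -2.67 (6.37-fold lower), FET3 at -2.62 (6.15-fold lower) and the hexose transporter genes HXT4 at -2.46 (5.49-fold lower) and HXT6 at -2.44 (5.44-fold lower). Of the DAN/TIR genes 4 of 9 were higher under pressure than in the cold and 0 lower, with a median of 0.58 (percentile 99.97), which was 0.19 with perfect-match intensities, where 2 were lower, and 1.40 among the 7 members above mismatch. Stress and reserve carbohydrate genes were lower under pressure for 14 of 24 and higher for 1, with a median of -0.64 (percentile 0).

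Amino acid permease genes were lower under pressure than in the cold for 7 of 16 and higher for 0, with a median of -0.46 (percentile 0.01), and iron uptake genes for 5 of 11 with a median of -0.39 (percentile 0.67), which were -0.25 and -0.18 with the arrays centred. Glucose-repressed genes were lower for 4 of 14 with a median of -0.50 (percentile 0.04), respiration genes for 5 of 21 with -0.34 (percentile 0.06), histone genes for 2 of 10 with -0.34 (percentile 0.87), ribosomal protein genes for 9 of 137 with -0.23 (percentile 0) and PAU genes for 3 of 21 with -0.26 (percentile 1.56). None of these 5 lists had a member higher under pressure past 1.5-fold. With the arrays centred their medians were -0.29, -0.13, -0.13, -0.024 and -0.053, and respiration had 2 members higher and 2 lower. Alpha-specific genes were higher under pressure for 3 of 4 with a median of 1.20 (percentile 100), amino acid biosynthesis genes for 9 of 20 with 0.45 (percentile 100) and ergosterol genes for 7 of 22 with 0.35 (percentile 99.99), and none of their members was lower, but these medians were 0.79, 0.10 and 0.038 with perfect-match intensities. Another 4 lists stood apart with small medians that turned negative with perfect-match intensities: hypoxic genes, which did not stand apart without the length trend, from 0.14 to -0.11, methionine and sulfur genes from 0.21 to -0.11, phosphate-response genes from 0.16 to -0.16, and hexose transport and glycolysis genes from 0.11 to -0.25. Percentiles of the other lists were 90.9 for chaperones, 72.6 for fatty acid and phospholipid genes, 41.2 for ribosome biogenesis, 4.86 for other cell wall genes, 86.0 for a-specific genes, 11.4 for meiosis genes and 95.0 for the deleted markers.

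Past 1.5-fold, 205 genes were higher and 486 lower under pressure than in the cold among 4799 counted, with a median ratio of -0.12 (SD over genes 0.40). The split was 426 higher and 210 lower with the arrays centred, 278 and 286 with quantile normalization of the gene values, and 84 and 818 with perfect-match intensities.

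The last comparison asked how far the responses to pressure and to cold share genes. Of 4807 genes counted in both, 1166 were higher in both, STF2, EGO4, RGI1, COX5B, COX17 and TIR1 among them, and 351 were lower in both, DBP2, PRM7, BSC1, AAH1, HXT2 and TAT1 among them. For these main values, lists of the same sizes drawn independently would share 459 and 58.3 genes, and unchanged arrays against a shared control gave means of 112 and 117. The shared counts were 580 and 975 with the arrays centred, 752 and 644 with quantile normalization, and 1043 and 88 with perfect-match intensities. Higher under pressure and lower in the cold were 0 genes, and lower under pressure and higher in the cold were 11, against means of 5.56 and 5.53 and at most 11 and 12 for unchanged arrays against a shared control, which itself makes opposite calls rare, with HXT4, HXT6 and HXT7 among the 11. The simulated noise holds the real differences between the treated arrays, so it cannot tell real opposite responses from none. With the arrays centred the observed opposite counts were 12 and 7, with 5 of the 11 kept, and with perfect-match intensities 1 and 9, with 3 of the 11 kept (GRE1, HSP26 and ALD3, chosen after their values were seen). Across genes, which are not independent replicates, the log2 ratios of the responses had a Pearson r of 0.866 and a Spearman rho of 0.844, against 0.506 and 0.482 for unchanged arrays. Their covariance was 0.576, against 0.0924 for unchanged arrays, a difference of 0.484. Part or all of this excess may come from a deviation of the shared control, which cannot be split off because it is 1 array. The SD of the log2 ratios over genes was 0.75 and 0.73 against the control and 0.40 between the treated arrays. The correlation restates this larger distance of the control array from both. Log2 ratios to the control were also higher for shorter genes, with a Spearman rho with gene length of -0.286 under pressure and -0.323 in the cold, but 0.0495 between the treated arrays.

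**Figure D3:**
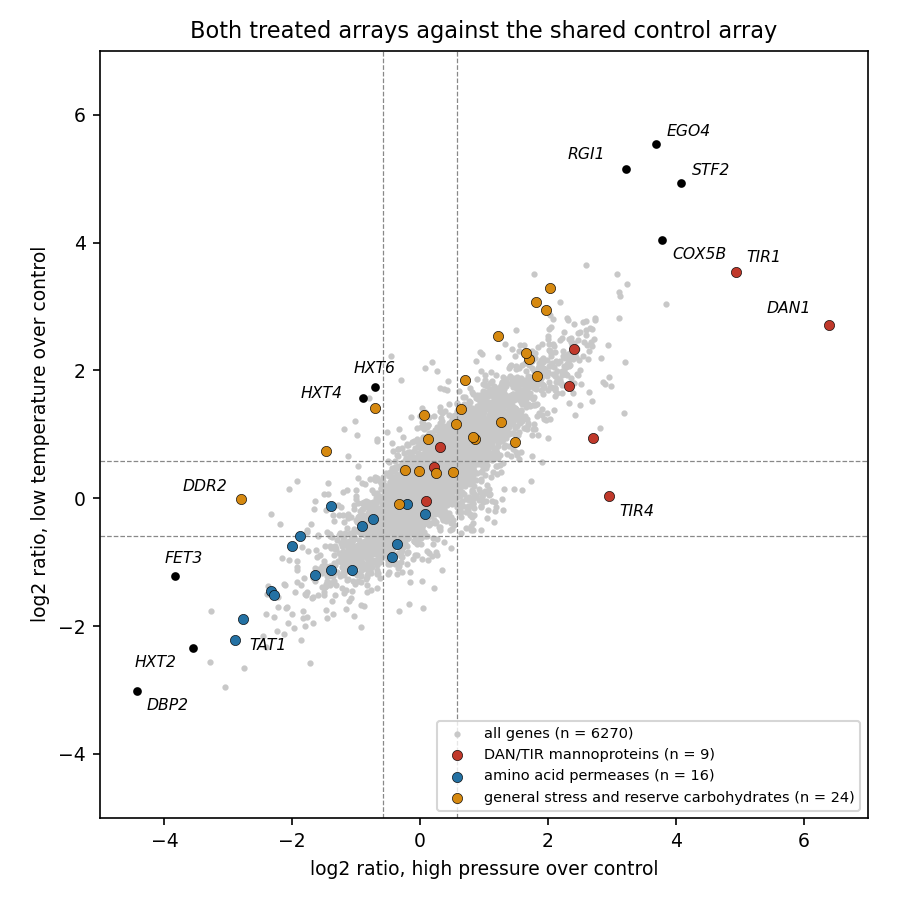
Log2 ratio to the control under high pressure (x axis) and at low temperature (y axis) of 6270 genes, 1 grey point per gene, with 3 gene lists in colour, some genes named and dashed lines at 1.5-fold. Points run along the diagonal (Pearson r 0.866 over the 4807 genes counted in both), DAN1 lies at 6.40 and 2.70, TIR4 at 2.95 and 0.04, and HXT4 at -0.90 and 1.56.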

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

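The tests in this part were set before their results were seen, except the simulated count of genes on opposite sides, the size of the trend on level, the perfect-match ratios, the removal of the trend on gene length and the percentile of the stress list without 3 of its members. The genes GRE1, HSP26, ALD3, CTT1, PHM7, CPP3, YNL194C and YNL195C were chosen after their values were seen.

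Past 1.5-fold, 11 genes lay below the control under high pressure and above it at low temperature, no more than the 12 that unchanged arrays against a shared control reached in 100 simulations (mean 5.53). The noise of those simulations was drawn from the differences between the 2 treated arrays, real ones included. They therefore cannot tell the 11 from no opposite response. The difference between the responses was not tested, since each condition has 1 array. The hexose transporter genes HXT4, HXT6 and HXT7 had log2 ratios of -0.90, -0.71 and -0.80 under pressure and 1.56, 1.73 and 1.57 in the cold. HXT6 and HXT7 are near-identical copies, so their probes read both and they count as 1 observation. The stress genes HSP26, a small chaperone, CTT1, the cytosolic catalase, GRE1, a hydrophilin, and ALD3, an aldehyde dehydrogenase, had -1.01, -0.71, -1.18 and -1.47 under pressure and 1.20, 1.41, 1.08 and 0.74 in the cold. CPP3 had -1.13 and 0.66. HSP26 was not above mismatch under pressure, so its -1.01 carries the same caution as a ratio given with "at least". The other 3 genes have no fold, as they were above mismatch on neither array of at least 1 comparison: log2 levels on the control, high-pressure and low-temperature arrays were 7.16, 6.18 and 8.16 for PHM7, 7.11, 6.43 and 8.03 for YNL194C, and 7.84, 7.16 and 8.73 for its chromosome XIV neighbour YNL195C. With perfect-match intensities 3 of the 11 (GRE1, HSP26 and ALD3) stayed on opposite sides past 1.5-fold, while HXT4, HXT6 and HXT7 had -0.12, -0.074 and -0.37 under pressure. With the arrays centred 5 stayed so, and without the trend on gene length 5.

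The 5 genes lowest under pressure relative to cold, DDR2, RTN2, FET3, HXT4 and HXT6, were weighed as a pattern. A level-dependent scaling between the treated arrays could account for a small part of these ratios alone. The trend of the ratio on level over all genes was at most 0.21 on the log2 scale (at most 0.23 in 100 resamplings of the genes), while each of the 5 ratios was at least 2.44 in size. The 5 were picked as extremes of ratios with an SD over genes of 0.40, so a trend of their size could hardly occur and the test is weak. Lower general stress expression under pressure than in the cold was weighed for DDR2. The stress list had a median log2 ratio of -0.64, at percentile 0 of matched random lists, and still -0.60 at percentile 0 without DDR2, CTT1 and ALD3. These 3 were the only members of the list lower than the control past 1.5-fold under pressure, so leaving them out favours a higher median. Against the control, the whole list had medians of 0.68 under pressure and 1.17 in the cold. Without the 3 these were 0.82 and 1.19. DDR2 lay at 13.31 in the control, 10.51 under pressure and 13.29 in the cold. The shift of the list therefore does not account for the fall of DDR2. Whether lower expression of glucose-repressed genes goes with HXT6 stays open, since that list without HXT6 and HXT7 had a median of -0.38, at the 1.01 percentile, but 3 of its 12 members were above mismatch. A technical difference between these 2 arrays remains open, because no array was repeated.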

How the results depend on the processing

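The perfect-match intensities, the restriction to genes above mismatch and the removal of trends on level or gene length were chosen after seeing the data. The 10 highest and 10 lowest genes of each comparison with the control, and the 5 and 5 of pressure against cold, kept their sign under all alternatives that give ratios. The smallest absolute log2 ratio among them was 0.724. Pearson r of the responses ranged from 0.829 to 0.874. Dropping the filter on dim genes, filtering at the array median, and using the first row of each gene left every count within 1.5 times. The next counts are pooled over the alternatives, so each list median or gene ratio counts once per alternative. Of list medians, 383 stayed within 0.25 with the same sign and 10 changed sign in lists that stood apart. Another 159 moved otherwise, 56 of them to the other sign in lists that did not stand apart. Of ratios of named genes, 917 kept their sign and their side of 1.5-fold, 83 did not keep both and 1, of HIS3, changed sign from past 1.5-fold. Using the first row of each gene left all 69 medians and 143 ratios unchanged in this sense, which raises the pooled counts. On the arrays 54.2% to 62.4% of rows were above mismatch. Counts below are given as higher then lower, and where no other cause is named the cause was not tested.

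A stricter threshold lowers counts by construction. At 2-fold they were 729 and 251 for pressure against control, 918 and 183 for cold against control, 60 and 109 for pressure against cold, and 607 and 124 for both treatments. At 3-fold they were 279 and 75, 349 and 40, 7 and 26, and 224 and 27. Adding 100 shrinks ratios of dim genes by construction, to 757 and 382 for pressure, 846 higher for cold, 154 lower for pressure against cold, and 592 and 232 for both.

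With the arrays centred, the shift of the medians gave 840 and 1231, 721 and 1497, 426 and 210, and 580 and 975 for both. Centring brought DAN4 and PAU7 in the cold inside 1.5-fold at 0.25 and 0.45, and STE3 under pressure to 0.58. HHF2 lay at 0.58 under pressure and 0.55 in the cold. Centring brought the DAN/TIR median to 2.07 under pressure and 0.39 in the cold, and ribosomal protein genes to -0.25 and -0.23. The median gene moved with them, to -0.21 and -0.29, so the place of these lists among random lists did not change. Quantile normalization of the gene values gave 917 lower under pressure, 991 and 969 in the cold, 286 lower for pressure against cold, and 752 and 644 for both.

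Perfect-match intensities gave 257 lower under pressure, 113 lower in the cold, 84 and 818 for pressure against cold, and 88 lower in both. The DAN/TIR median was 2.03 under pressure and 0.19 for pressure against cold with them. FET3 and FKS1 in the cold both lay at -0.23, and HXT6 and HXT7 under pressure at -0.074 and -0.37. PAU22 in the cold lay at 0.19 and SPS4 under pressure at -0.17. Medians changed sign to 0.070 for ribosome biogenesis and 0.20 for amino acid biosynthesis in the cold. For pressure against cold they changed to -0.11 for hypoxic genes, -0.11 for methionine and sulfur genes, -0.16 for phosphate-response genes and -0.25 for hexose transport and glycolysis. Restricting to genes above mismatch leaves fewer members, and the DAN/TIR median became 2.71 under pressure and 1.40 for pressure against cold.

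Without the trend on level, counts were 1074 and 821 in the cold, 276 lower for pressure against cold and 563 lower in both. Without the trend on gene length they were 977 and 877 in the cold, 279 lower for pressure against cold, and 703 and 584 in both. The DAN/TIR median was then 2.01 under pressure, ribosomal protein genes lay at -0.22 and -0.20, and HIS3 in the cold lay at -0.0014.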

Other observations

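The gene groups in the next paragraphs, the test of glucose exhaustion and the tests of a trend as the whole cause were chosen after the result was seen.

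Several gene groups outside the lists above lay on the same side of the control on both treated arrays by the main values. Both comparisons use the same control array, so a deviation of that array alone could give this. Proteasome genes (named PRE, PUP, RPN or RPT) were higher for 26 of 33 under pressure and for 28 of 33 in the cold, and none was lower. Their median log2 ratios were 1.10 and 1.00, at percentile 100 of matched random lists in both, and 0.76 and 0.45 with the arrays centred, where 23 and 15 were higher and 0 and 2 lower. PRE1, a subunit of the proteasome core, was higher by 1.86 under pressure and 1.87 in the cold. Mitochondrial ribosomal protein genes were higher for 44 of 67 under pressure and 51 of 67 in the cold, with 0 lower and medians of 0.81 and 1.08. These became 0.46 and 0.62 without the trend on gene length and 0.47 and 0.53 with the arrays centred, where 32 and 31 were higher and 3 and 0 lower. RNA polymerase I genes were lower for 5 of 7 under pressure and 4 of 7 in the cold, with 1 higher in each and medians of -0.95 and -0.65, and -0.45 and -0.06 with perfect-match intensities. Vacuolar ATPase genes were higher for 8 of 15 under pressure with a median of 0.87 (percentile 99.99) and for 7 of 15 in the cold with 0.40 (percentile 95.9), which became 0.53 and -0.15 with the arrays centred.

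Rows for the Gag gene of Ty retrotransposons set the treated arrays apart. Under pressure 38 of 42 were higher and 0 lower, with a median of 0.83 (percentile 100), but 15 higher with a median of 0.49 with the arrays centred. In the cold 6 of 42 were higher and 0 lower, with a median of -0.07 (percentile 0.33) that was 0.28 with perfect-match intensities and -0.61 with the arrays centred, where 22 were lower. Between the treated arrays 28 of 42 were higher under pressure, with a median of 0.89 that was 0.58 with perfect-match intensities. These rows are near-identical copies whose probes read the same transcripts, so they count as far fewer than 42 independent genes. The 8 rows for the Gag-Pol gene of Ty had a median of 0.64 under pressure, with the lowest row at 0.40 (4 higher, 0 lower). They did not stand apart there (percentile 95.5) or in the cold (median 0.12, percentile 32.5). Between the treated arrays 5 of the 8 were higher under pressure and 0 lower, with a median of 0.71 (percentile 100). With 8 rows against 42, the percentiles do not show that Gag and Gag-Pol rows differ. Genes named for purine synthesis (11 genes, percentiles 57.3 and 75.1) and flocculins (6 genes, percentiles 28.9 and 33.9) did not stand apart in either comparison with the control.

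The large response that both treated arrays share against the control was weighed as a pattern: 1517 genes were past 1.5-fold the same way in both, against at most 281 in 100 simulations in which the control array was as noisy as the treated arrays. Without the trend on level 1149 of these genes (a share of 0.757) stayed past 1.5-fold in both, and without the trend on gene length 1033 (0.681), each far above 281, which argues against either trend as the whole cause unless the control array is noisier than the treated arrays. How much of the pattern a trend of the control array accounts for cannot be told apart from a real response, because the shares lie between the limits set beforehand (0.5 and 0.75) or, for level, within counting error of the upper limit. Glucose exhaustion during the 5 h incubation stays open, since the glucose-repressed list, at percentile 9.28 under pressure and 89.9 in the cold, lay inside the range of random lists with 4 and 6 of its 14 members above mismatch. The design leaves open that the control, with no stated 5 h incubation and 1 array, may differ from both treated arrays by culture age or by hybridisation, alongside a shared effect of pressure and cold.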
